A study of Mus musculus with 16 samples.

How the data were processed

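RNA sequencing libraries were made from snap-frozen liver of 16 male Ercc1Δ/− mice aged 11 weeks, with 4 animals on each of 4 diets. Ercc1 encodes a subunit of an endonuclease of nucleotide excision repair, and mice with 1 truncated and 1 null allele age prematurely. The animals were F1 hybrids of C57BL6J and FVB. Per the labels' protocols, all animals received the AIN93G reference diet until 8 weeks of age and were then randomised to that diet (control) or to a diet high in protein and low in carbohydrate, low in protein and high in carbohydrate, or low in fat and high in carbohydrate. Groups were taken from the sample titles, which number the animals of each diet from 1 to 4. Libraries were prepared with a directional kit.

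The authors deposited 1 table of whole-number read counts per gene for all 16 libraries, with gene positions and summed exon length. Per the submitters' processing notes, Trimmomatic 0.39, STAR 2.7.0f, featureCounts, Subread 1.6.4 and edgeR 3.32.1 were used with build GRCm38.p6. Their settings, the strand setting of the counting and the annotation release are not given in the sources used here. Without a stated strand setting, reads of overlapping antisense genes cannot be told apart, and genes with near-identical copies (the Mup, Cyp2 and Hbb families and ribosomal protein genes with many pseudogenes) are uncertain for the way shared reads were counted. The table holds 54752 genes, of which 53861 matched an identifier with its version in GENCODE M21, all at the same start and end. The M21 annotation supplied symbols, biotypes and GC content here.

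Library totals ran from 35243594 to 112789127 counts. In edgeR 4.0.16 (R 4.3.3), genes passing filterByExpr on the group (17833) were normalised with TMM factors and fitted with the quasi-likelihood model, with 4 group means and all 16 libraries in 1 fit (12 residual degrees of freedom). The 6 pairs of diets were tested as contrasts and the 3 diets were tested against control together, all two-sided, with Benjamini-Hochberg adjustment within each comparison at 0.05. Values in CPM, the usual depth-scaled counts, use TMM-scaled library sizes unless stated otherwise, and fold changes are from the edgeR fit with their standard errors (SE). The labels do not say how the animals shared litters or cages, so p-values measure the spread between these samples.

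Before the data were examined, 37 gene lists (26 metabolic and stress programs and 11 cell type marker lists) were fixed. Each was tested with camera of limma 3.58.1 on voom log-CPM with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera compares a list with all other genes. Where members of a list move together, a count of members in 1 direction is not repeated evidence. Estimated correlation and fry, which tests whether the genes of a list move 1 way on balance, were alternatives. Adjusted p-values over the list alone were computed from the edgeR p-values of its members, with no adjustment over the 37 lists. The series title names a gene-length-dependent decline of transcription, so a length slope was computed in each library as the least-squares slope, across 14252 protein-coding genes on the autosomes and X, of the deviation of log2 CPM (prior count 2) from its mean over the 16 libraries on log10 genomic length. Group means of the slopes were compared by exact two-sided permutation of 8 libraries (70 assignments, smallest possible p 0.029), adjusted over the 6 comparisons. Fold changes against the shared control were compared with simulated unchanged groups (50 draws) and with the controls divided 2 and 2.

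Genes were to be named by a rule: the most changed genes past the threshold whose libraries did not overlap, and, for each list with no member past it, up to 2 members with the smallest p. As no gene passed, the named genes come from the lists, and some genes that the rule names are not reported here. Gm30692, Arid5b, Alas1, Noct, Eva1a, Slc7a2, AB124611, Gm14097, 4930544F09Rik, Bud13, Btbd19 and Srms were chosen after their values were seen, as the smallest p-values or as the few genes called under an alternative.

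The steps were tested on simulated data. Of 50 genes changed by each fold between the high-protein and control groups of simulated counts (17833 genes), edgeR recovered 6 at 1.5-fold, 21 at 2-fold, 46 at 4-fold and 48 at 8-fold, with 2 false calls. A slope of -0.12 put into high-protein libraries was recovered as -0.127 (14252 genes), and with none put in the difference was -0.007. These counts were drawn independently for each gene, with 1 spread per gene for all diets. They lack the wider spread of the real controls and the slope differences between real libraries of a diet (SD 0.056 to 0.115). They therefore check the steps and do not show how readily such changes would be found in the real data. The alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom with sample quality weights, no low-count filter, a filter of over 1 CPM in at least 4 libraries, fits of the compared groups only, the replicate number as a block, the library number as a covariate, each library left out in turn and, for the slope, exonic length, all biotypes, a mean of at least 5 CPM, further predictors, a prior count of 0.5 and rank correlation. Leaving out control 3 and 4 or control 4 and high-protein 4, a kidney score as a covariate, kidney-associated genes left out, DESeq2 with no low-count filter, leaving out single libraries for the kidney level, and leaving out libraries of groups outside a comparison were added after seeing the data, as were a kidney list of 20 genes, a glucocorticoid and fasting response list of 22 genes and lists of 5 other tissues. CPM of kidney genes use library totals.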

Results

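Liver transcriptomes of 16 male Ercc1Δ/− mice were compared between 4 diets, with 4 animals per diet. Library totals were 35243594 to 46051218 counts in control, 37317405 to 46899907 with high protein, 36662347 to 43404769 with low protein and 36871852 to 112789127 with low fat, where replicate 2 was the deepest library. Replicates differed from each other by more than sampling noise in every group, with a chi-square per degree of freedom of 46.3 or more over 17140 to 17150 genes. Control 4 lay farthest from its group, with a standard deviation of 1.17 log2 units over genes from the other 3 controls, against 0.58 for control 1, 0.61 for control 2 and 0.85 for control 3. Of the variance between libraries, 31.2% fell on a first principal component on which control 4 was the lowest library.

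Ercc1 (chromosome 7, 19344778 to 19356524, GRCm38), the gene altered in all animals, was counted 46 to 175 times per library. Its level was 1.64 ± 0.334 CPM in control (SD, n = 4), 1.6 ± 0.239 with high protein, 1.56 ± 0.269 with low protein and 1.65 ± 0.272 with low fat. As every animal carried the same genotype, these values describe the libraries and check no contrast.

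Transcripts of kidney were present in the liver libraries. The summed level of 20 kidney genes, among them Umod and Slc12a1 of the thick ascending limb and Kap and Slc34a1 of the proximal tubule, ran from 2.73 CPM of library totals in high-protein 1 to 5630 CPM in control 3. The 4 low-fat libraries held 1090 to 3320 CPM and the low-protein libraries 722 to 1350 CPM. The high-protein libraries other than replicate 1 held 450 to 1670 CPM and the controls other than replicate 3 held 95.5 to 279 CPM. The summed level on the log2 scale differed from control by -0.87 with high protein, 1.26 with low protein and 2.34 with low fat, with exact permutation p-values of 0.771, 0.457 and 0.143, adjusted over 6 comparisons to 0.771, 0.549 and 0.286. It differed by -2.13 between high and low protein (exact permutation p = 0.371, adjusted 0.549), by -3.21 between high protein and low fat (exact permutation p = 0.057, adjusted 0.257) and by 1.08 between low fat and low protein (exact permutation p = 0.086, adjusted 0.257). Single libraries moved the kidney level differences. Without high-protein 1 that of high protein was 1.1 and without control 3 it was 0.39, both in the other direction, and without control 2 or high-protein 2 or 4 it was -1.57, -1.83 and -1.55. Without control 3 the kidney level difference was 2.51 with low protein and 3.6 with low fat, each with an exact permutation p of 0.029, the smallest possible, and without control 2 that of low protein was 0.56. Without high-protein 1 the kidney level differed by -0.16 between high and low protein and by -1.24 between high protein and low fat, and the latter was -4.17 without high-protein 2 and low fat against low protein 1.4 without low-fat 1, each with an exact permutation p of 0.029.

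**Figure D1:**
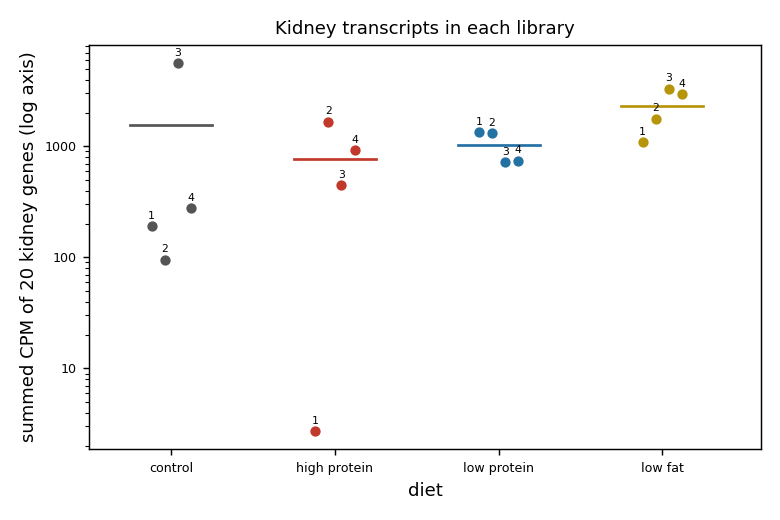
Summed level of 20 kidney genes in each liver library, in CPM of library totals on a log axis, by diet, with 4 libraries per diet (numbered points) and their mean (line). Control 3 has the highest level (5630 CPM) and high-protein 1 the lowest (2.73 CPM).

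The high-protein diet was compared with control to ask how replacing carbohydrate with protein alters liver expression. Genes of fatty acid oxidation and PPAR-alpha targets were higher with high protein, with 27 of 30 above control and a median log2 fold change of 0.37. Slc25a20, the mitochondrial carnitine carrier, was at 114.7 ± 22.5 CPM against 73.49 ± 8.04 (SD, n = 4; log2 fold change 0.64, SE 0.14), and Cpt2, which completes the transfer of fatty acids into mitochondria, was at 153.8 ± 21 against 108.5 ± 20.4 CPM. In lipogenesis 18 of 21 genes were below control, with a median of -0.70. Acacb, the acetyl-CoA carboxylase at the mitochondrial surface, was 3.27-fold lower at 21.26 ± 1.3 against 69.49 ± 24.4 CPM, and Pnpla3, a lipid droplet acyltransferase and hydrolase, was 5.93-fold lower, at 0.2639 ± 0.142 against 1.59 ± 1.39 CPM. Of cytosolic ribosomal proteins 74 of 77 were above control (median 0.20) and of the nuclear-encoded respiratory chain 55 of 60 (median 0.22). High-protein 4, the highest of the 16 libraries for both lists (0.44 and 0.48), had the lowest length slope (-0.113).

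Camera called 11 of the 37 lists in this comparison, 10 higher and 1 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.649. Fatty acid oxidation and PPAR-alpha targets (camera adjusted p = 1.27e-11, adjusted p = 0.649 with an estimated correlation) kept the camera call with any 1 library left out. So did cytosolic ribosomal proteins (in the same order 2.44e-14 and 0.688), nuclear-encoded respiratory chain (7.23e-11 and 0.688) and erythroid cell genes (0.00117 and 0.649). The first list was called higher with every diet against control. It was not called for high protein against low protein (camera adjusted p = 0.134) or low fat (0.101). Its medians were -0.08, -0.15, 0.24 and 0.4 in high-protein 1 to 4 and -0.24 to -0.13 in control. Erythroid cell genes were higher in 5 of 6, with Hbb-bt at 2.19-fold and Hbb-bs at 2.03-fold, globin chains of red blood cells with shared sequence. The adjusted p of erythroid cell was 0.103 when control 4 and high-protein 4 were left out together. Lipogenesis (0.000407 and 0.688) had an adjusted p of 0.0729 without control 1 and 0.055 without control 3. Adjusted over the list alone, 6 members of lipogenesis passed, 2 of fatty acid oxidation and PPAR-alpha targets, and 0 of either ribosomal or respiratory list.

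The interferon response was higher with high protein in 26 of 30 genes (camera adjusted p = 1.1e-05, adjusted p = 0.688 with an estimated correlation), with Irf7, a transcription factor of this response, at 1.52-fold and Mx1, an antiviral GTPase, at 1.8-fold. The adjusted p of interferon response without control 4 was 0.677. T and NK cell markers were higher in 11 of 13 (in the same order 0.00507 and 0.688), with the interleukin receptor chain Il2rb at 1.77-fold. For T and NK cell the adjusted p was 0.184 without control 4. Kupffer cell markers were higher in 12 of 13 (0.0064 and 0.688), with the folate receptor Folr2 at 1.63-fold. For Kupffer cell the adjusted p was 0.063 without control 4 and 0.0758 without high-protein 3. The recruited macrophage and neutrophil list was higher in 9 of 14 (0.0346 and 0.649). Lyz2, a myeloid lysozyme, was at 0.43 ± 0.19 log2 units (SE) and the tetraspanin Cd9 at -1.03 ± 0.38, or -0.3 without control 4. For recruited macrophage and neutrophil the adjusted p was 0.0679 without control 1, 0.127 without control 2, 0.0672 without control 3, 0.178 without control 4, 0.177 without high-protein 1, 0.0758 without high-protein 3 and 0.0624 with the kidney score as a covariate. The mitochondrially encoded genes were higher in 10 of 13 (0.0123 and 0.742), with mt-Nd3 at 1.39-fold. For mitochondrially encoded genes the adjusted p was 0.43 without control 2 and 0.519 without high-protein 3. High-protein 1 and control 3, the libraries with the least and the most kidney transcripts, are both in this comparison.

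Amino acid catabolism was called higher (camera adjusted p = 0.0367, adjusted p = 0.742 with an estimated correlation), while its median log2 fold change was 0.01 and its mean was -0.10. Its member Sdsl, a serine dehydratase, was at 12.48 ± 4.04 against 35.55 ± 53.7 CPM, and Sardh, a sarcosine dehydrogenase, was at 1110 ± 131 against 875 ± 119 CPM. The adjusted p of amino acid catabolism was 0.0729 without control 1, 0.987 without control 3, 0.177 without high-protein 1, 0.348 without high-protein 4 and 0.107 with the kidney score as a covariate. Sdsl without control 4 was at a log2 fold change of 0.51. Cholesterol synthesis was not called (adjusted p = 0.0945, median -0.38), although Lss, lanosterol synthase, was at 41.84 ± 5.43 against 62.99 ± 6.94 CPM and passed adjusted over the list alone (0.0104, edgeR). Without control 4, cholesterol synthesis had an adjusted p of 1.31e-11. Slc25a13, the aspartate and glutamate carrier that feeds the urea cycle, passed adjusted over the list alone (1.26-fold, 0.0302). So did the p53 targets Ddb2, a damage sensor of nucleotide excision repair (1.53-fold, 0.0354), and Sesn1 (0.0354). Sesn1 was at 11.41 ± 1.36 against 105.5 ± 184 CPM, a log2 fold change of -3.21 that was -0.23 without control 4. The nucleotide excision repair list was not called and 0 members passed, Ercc8 of transcription-coupled repair (0.654-fold) included.

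No single gene passed over all genes. edgeR called 0 of 17833 genes between high protein and control, with 1109 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.762, while DESeq2 called 1. The unadjusted count was 1865 without control 2, 2056 without control 3 and 336 with the compared groups alone. The DESeq2 gene was Gm30692, chosen after its values were seen, at 0.2307 ± 0.0944 against 1.395 ± 0.938 CPM. The share of genes whose 4 high-protein libraries all lay to 1 side of the controls was 1.96%, against 2.86% by chance.

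The series title concerns gene length. In high-protein livers the median log2 fold change against control was 0.04 for the 3473 genes under 10 kb, -0.05 for 10 to 30 kb, -0.12 for 30 to 60 kb, -0.15 for 60 to 100 kb, -0.15 for 100 to 200 kb and -0.18 for the 689 genes over 200 kb. The mean length slope per library was -0.069 ± 0.056 log2 units per 10-fold of genomic length with high protein (SD, n = 4), 0.045 ± 0.103 in control, -0.024 ± 0.073 with low protein and 0.048 ± 0.115 with low fat. The high-protein slope differed from control by -0.115 (exact permutation p = 0.114, adjusted 0.343) and from low fat by -0.117 (exact permutation p = 0.086, adjusted 0.343), where the smallest p that the 70 assignments allow is 0.029. The difference from low protein was -0.045 (exact permutation p = 0.286, adjusted 0.446). Low protein differed from control by -0.070 (exact permutation p = 0.314, adjusted 0.446), low fat from control by 0.002 (exact permutation p = 0.971, adjusted 0.971) and low fat from low protein by 0.072 (exact permutation p = 0.371, adjusted 0.446). Leaving out 1 library moved several of these length slope differences. Low protein against control was -0.117 without control 2, -0.041 without control 3 and -0.044 without low-protein 4, and high protein against low fat was -0.061 without low-fat 3. High against low protein was -0.018 without low-protein 1, -0.071 without low-protein 4 and -0.073 without high-protein 2, and low fat against low protein was 0.016 without low-fat 3 and 0.047 without low-protein 4. Low fat against control lay between -0.053 without low-fat 3 and 0.032 without low-fat 1. The slope of high-protein 2 was 0.013 and that of control 2 was -0.095, so the libraries of these groups overlapped. The difference of genes over 100 kb from genes under 10 kb was -0.17 log2 units between high protein and control (exact permutation p = 0.114, adjusted 0.343). Across genes, which are not independent replicates, the Spearman correlation of length with the fold change was -0.22 for high protein, -0.14 for low protein and -0.02 for low fat against control, -0.11 for high against low protein, -0.16 for high protein against low fat and 0.12 for low fat against low protein.

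**Figure D2:**
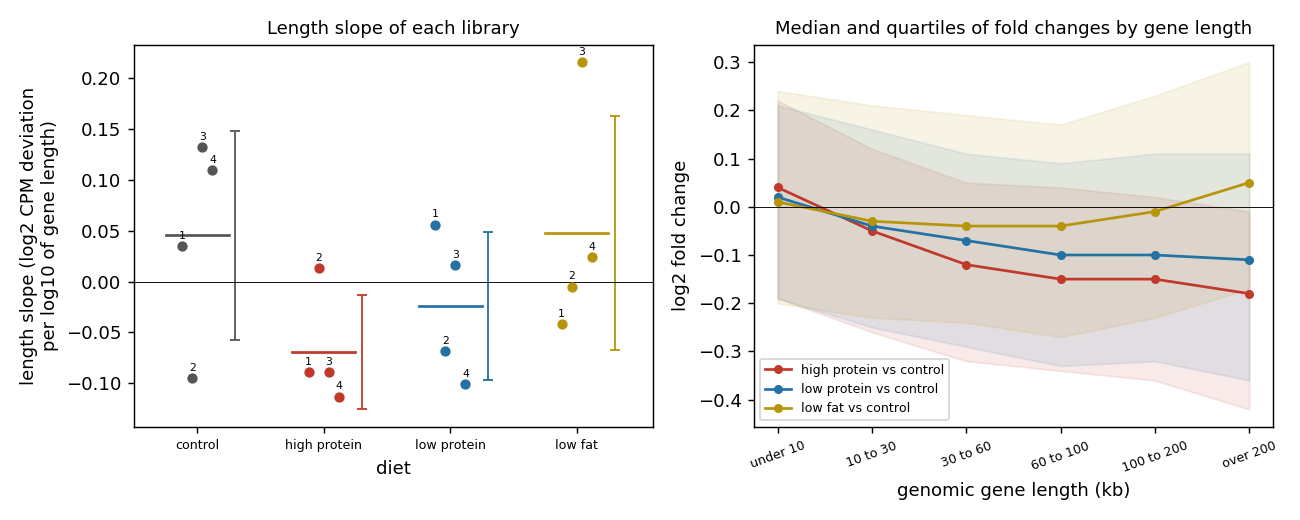
Left, length slope of each library (log2 CPM deviation per log10 of genomic gene length, numbered points) with the mean and SD of each diet. Right, median log2 fold change against control by gene length in kb, with quartiles shaded. The mean is -0.069 with high protein and 0.045 in control, and the points of these groups overlap.

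The low-protein diet (protein 70% of standard, carbohydrate 112%) was compared with control to ask about less protein. The high-protein diet had 194% and 70%, so the changes in protein were unequal. Urea cycle genes were lower in 6 of 8, with a median log2 fold change of -0.71. Ass1, argininosuccinate synthase, was at 2355 ± 344 against 5107 ± 3260 CPM (SD, n = 4) and Cps1, which makes carbamoyl phosphate for the cycle, was at 3664 ± 185 against 6237 ± 2770 CPM. Amino acid catabolism was lower in 40 of 54 genes (median -0.16), and gluconeogenesis in 8 of 10 (median -0.49), with Got1, the cytosolic aspartate aminotransferase, 8.4-fold lower at 258.9 ± 60.3 against 2173 ± 3490 CPM and Ppargc1a, a coactivator of gluconeogenic genes, 4.18-fold lower. Periportal hepatocyte genes were lower in 11 of 14, with the serine dehydratase Sds at 126.7 ± 44.4 against 680.6 ± 973 CPM and Sdsl at 7.096 ± 0.798 against 35.55 ± 53.7 CPM. Without control 4 the log2 fold change went from -3.07 to -0.75 for Got1, from -2.06 to -0.82 for Ppargc1a, from -2.43 to -0.63 for Sds, from -2.32 to -0.31 for Sdsl, from -1.12 to -0.59 for Ass1 and from -0.77 to -0.44 for Cps1. Fatty acid oxidation and PPAR-alpha targets were higher in 24 of 30 (median 0.17), with the pantetheinase Vnn1 at 40.06 ± 9.85 against 20.05 ± 7.69 CPM.

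Camera called 11 lists, 7 higher and 4 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.393. With an estimated correlation, each list named in this paragraph had an adjusted p of 0.657. Amino acid catabolism (camera adjusted p = 0.000984), fatty acid oxidation and PPAR-alpha targets (1.99e-05) and T and NK cell (0.000984) kept the call with any 1 library left out. The calls of urea cycle (0.00613), gluconeogenesis (0.013) and periportal hepatocyte (0.013) were lost without control 4. The adjusted p was then 0.0616 for urea cycle, 0.237 for gluconeogenesis and 0.0616 for periportal hepatocyte. The list periportal hepatocyte also had 0.0648 without control 2 and 0.0546 with the kidney score as a covariate. For gluconeogenesis the adjusted p was 0.0584 without low-protein 3. Control 4 held 9960 CPM of Ass1, 7400 of Got1 and 2140 of Sds, against at most 3920, 573 and 206 in the other controls. Adjusted over the list alone, 3 members passed in urea cycle, 3 in gluconeogenesis and 5 in periportal hepatocyte.

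T and NK cell markers were higher in 12 of 13, with Cd3d of the T cell receptor complex at 0.2608 ± 0.0828 against 0.06406 ± 0.0746 CPM (log2 fold change 2.04, and 2.79 without control 2) and Trbc2, a T cell receptor constant region, at 1.86-fold. B cell markers were higher in 10 of 11 (camera adjusted p = 0.0214, adjusted p = 0.657 with an estimated correlation), with Ms4a1 at 3.33-fold and Cd79a at 2.28-fold, at levels under 1 CPM. For B cell the adjusted p was 0.104 without control 1, 0.179 without control 2, 0.0838 without low-protein 1, 0.0546 without low-protein 4 and 0.0522 with the kidney score as a covariate. Kupffer cell markers were higher in 10 of 13 (in the same order 0.0319 and 0.657). Folr2 was at 1.53-fold and Adgre1, the macrophage antigen F4/80, at 1.36-fold (log2 fold change 0.44, and 0.21 without control 4). For Kupffer cell the adjusted p was 0.0957 without control 1, 0.0559 without control 2, 0.0697 without control 4, 0.368 without low-protein 4 and 0.063 with the kidney score as a covariate. Interferon response was higher in 28 of 30 (6.25e-05 and 0.657), with Mx1 at 1.8-fold and the GTPase Gbp2 at 1.44-fold. For interferon response the adjusted p was 0.577 without control 4, and the log2 fold change of Gbp2 went from 0.52 to 0.25. Male-biased liver genes were higher in 19 of 22 (0.000984 and 0.732), with the urinary protein Mup3 at 1.28-fold (log2 fold change 0.36, and 0.11 without control 4). For male-biased liver genes the adjusted p was 0.981 without control 4 and 0.0584 without low-protein 3. Senescence and secretory genes were higher in 10 of 12 (0.017 and 0.393). For senescence and secretory genes the adjusted p was 0.0626 without control 1 and 0.114 without control 3. Cdkn1a, the cell cycle inhibitor p21, was at 16.69 ± 1.31 against 149 ± 270 CPM, and its log2 fold change without control 4 was 0.25.

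Of the growth hormone and IGF axis, which was not called as a list, 4 members passed adjusted over the list alone. Socs2 and Cish, feedback inhibitors of growth hormone signalling, were 6.98-fold and 6-fold lower, with Cish at 7.978 ± 4.73 against 47.99 ± 13.9 CPM. Control 4 held 361 CPM of Socs2 against 28.3 to 73.3 in the other controls, and without it the log2 fold change of Socs2 went from -2.8 to -1.55. Over all genes, edgeR called 0 of 17833 between low protein and control, with 1262 at an unadjusted p under 0.05 and a smallest adjusted p of 0.682, while DESeq2 called 10. The unadjusted count was 2241 without control 1, 1907 without control 2, 2786 without control 3, 660 without control 4, 258 with the library number as a covariate and 547 with the compared groups alone. All low-protein library numbers (3, 5, 11 and 12) lie below those of the controls, so library order cannot be told apart from diet. The smallest p belonged to Arid5b (chromosome 10, 68092520 to 68278740), a DNA-binding regulator chosen after its values were seen, at 33.28 ± 3.24 against 115.2 ± 47.9 CPM. The libraries separated completely for 2.48% of genes, against 2.86% by chance.

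The low-fat diet was compared with control to ask about replacing fat with carbohydrate. Unfolded protein response genes were higher in 15 of 16 (median log2 fold change 0.50), with Creld2, an endoplasmic reticulum stress protein, at 81.06 ± 59.1 against 27.69 ± 17.6 CPM (SD, n = 4) and the chaperone Hyou1 at 318.8 ± 152 against 154.1 ± 70.0 CPM. Circadian clock genes were lower in 17 of 20 (median -1.01), with the repressor Ciart 8.63-fold and Per1 5.83-fold lower. Control 4 held 340 CPM of Per1 against 18.8 to 52.5 in the other controls, and without it the log2 fold change went from -2.54 to -1.01 for Per1 and from -3.11 to -1.9 for Ciart, which was at -4.14 without low-fat 4. That of Creld2 went from 1.55 to 0.94 without low-fat 2. Xenobiotic metabolism genes were lower in 18 of 21 (median -0.47), with the cytochrome Cyp2a5 at 348.9 ± 181 against 1043 ± 380 CPM. Urea cycle genes were lower in 7 of 8 and amino acid catabolism in 41 of 54, with Tat, tyrosine aminotransferase, at 752.5 ± 154 against 6112 ± 10100 CPM, Got1 at 258.1 ± 107 against 2173 ± 3490, Ass1 at 2772 ± 452 against 5107 ± 3260 and Cps1 at 4034 ± 263 against 6237 ± 2770 CPM. Control 4 held 21300 CPM of Tat against 938 to 1210 in the other controls, and without it the log2 fold change went from -3.02 to -0.49 for Tat, from -3.07 to -0.77 for Got1, from -0.88 to -0.36 for Ass1 and from -0.63 to -0.31 for Cps1. Immune and interferon lists leaned higher, with 0 called at an estimated correlation.

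Camera called 19 lists, 11 higher and 8 lower, fry called 2 (T and NK cell, and senescence and secretory genes), and 0 were called with an estimated correlation, where the smallest adjusted p was 0.25. Amino acid catabolism (camera adjusted p = 0.00017, adjusted p = 0.478 with an estimated correlation) kept the camera call with any 1 library left out. So did urea cycle (in the same order 0.00164 and 0.371), fatty acid oxidation and PPAR-alpha targets (0.000209 and 0.478) and unfolded protein response (4.22e-06 and 0.394). The same held for xenobiotic metabolism (0.000524 and 0.35) and circadian clock (0.000325 and 0.35). Without control 3 and 4 together, unfolded protein response had an adjusted p of 0.217 and circadian clock 0.125. Of periportal hepatocyte, not called as a list, 7 members passed adjusted over the list alone, with Ctsc higher and the rest lower. Among them control 4 stood far above the other controls for Pck1 (16300 CPM), Sds, Ass1 and Arg1. Adjusted over the list alone, 5 members of circadian clock, 4 of urea cycle, 3 of T and NK cell, 2 of xenobiotic metabolism, 1 of gluconeogenesis and 1 of B cell passed. In xenobiotic metabolism these included Cyp2b10, a cytochrome induced by xenobiotics, at 0.1029 ± 0.0577 against 8.45 ± 16.3 CPM, where control 4 alone held 32.9 CPM and the other controls at most 0.435, and the log2 fold change of Cyp2b10 went from -6.29 to -1.51 without it. Fatty acid oxidation and PPAR-alpha targets were higher in 22 of 30, with Vnn1 at 1.84-fold and the peroxisomal thiolase Acaa1b at 1.77-fold.

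Interferon response was higher in 29 of 30 (camera adjusted p = 3.05e-11, adjusted p = 0.35 with an estimated correlation), with Mx1 at 2.107 ± 0.863 against 1.079 ± 0.472 CPM and Gbp2 at 1.88-fold. T and NK cell markers were higher in 13 of 13 (in the same order 1.17e-06 and 0.25). Cd3d was at 5.66-fold and Trac, a T cell receptor constant region, at 3.41-fold. B cell markers were higher in 10 of 11 (0.00399 and 0.35). Cd79a was at 2.6-fold and the antibody light chain gene Igkc at 3.919 ± 4.7 against 0.7545 ± 0.494 CPM. Single libraries moved the log2 fold changes. Cd3d went from 2.5 to 3.25 without control 2. Trac went from 1.77 to 2.39 without control 3 and 1.17 without low-fat 2, and Igkc from 2.35 to 1.02 without low-fat 4. Kupffer cell markers were higher in 11 of 13 (0.000135 and 0.35). Folr2 was at 1.74-fold and the growth factor receptor Csf1r at 34.52 ± 4.1 against 25.03 ± 4.96 CPM. The recruited macrophage and neutrophil list was higher in 9 of 14 (0.0124 and 0.336). Lyz2 was at 1.51-fold and the neutrophil receptor Csf3r at 1.69-fold. These immune lists kept the call with any 1 library left out. Cholangiocyte markers were higher in 12 of 12 (0.00592 and 0.554), with Cftr at 2.15-fold (log2 fold change 1.1, and 2.7 without control 3). The cholangiocyte marker Epcam was at 15.4 CPM of library totals in control 3, the library with most kidney transcripts, and at 0.362 CPM in high-protein 1, which had the least. With the kidney score as a covariate the cholangiocyte difference turned to the other direction (adjusted p = 0.432); cholangiocyte also had 0.107 without control 1, 0.185 without control 2 and 0.0631 without low-fat 3.

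The remaining calls were lost without single libraries. Gluconeogenesis was lower in 10 of 10 (camera adjusted p = 0.0124, adjusted p = 0.541 with an estimated correlation), with Pck1, the rate-limiting gluconeogenic carboxykinase, at 2278 ± 446 against 5969 ± 6920 CPM (log2 fold change -1.39, and -0.17 without control 4). For gluconeogenesis the adjusted p was 0.252 without control 4 and 0.0629 without low-fat 3. Male-biased liver genes were higher in 22 of 22 (in the same order 0.000123 and 0.554). Elovl3 was at 3.09-fold (log2 fold change 1.63, and 3.73 without control 1) and Cyp4a12a at 1.71-fold (0.78, and 0.38 without control 4). For male-biased liver genes the adjusted p was 0.297 without control 4. Cell cycle genes were higher in 21 of 26 (9.99e-05 and 0.478), with the mitotic genes Ccnb2 at 1.93-fold and Cdk1 at 1.7-fold. For cell cycle the adjusted p was 0.0817 without control 4. Senescence and secretory genes were higher in 8 of 12 (0.0124, with an estimated correlation adjusted p = 0.25), with the chemokine Ccl5 at 2.35-fold and the stress hormone Gdf15 at 4.14-fold. For senescence and secretory genes the adjusted p was 0.0855 without control 1 and 0.0988 without control 3. Nucleotide excision repair was lower in 20 of 29 (0.0188, with an estimated correlation adjusted p = 0.35), with Ercc8 at 3.246 ± 0.472 against 5.023 ± 0.964 CPM. For nucleotide excision repair the adjusted p was 0.107 without control 1, 0.0527 without low-fat 4 and 0.0994 with the kidney score as a covariate. Cytosolic ribosomal proteins were lower in 74 of 77 (3.83e-07, with an estimated correlation adjusted p = 0.582), with Rps6 at 0.835-fold and Rpl12 at 0.852-fold, and nuclear-encoded respiratory chain genes in 51 of 60 (0.000209, with an estimated correlation adjusted p = 0.605), with Cox5a at 0.802-fold and Sdhb at 0.861-fold; without low-fat 3 the adjusted p was 0.0677 for cytosolic ribosomal proteins and 0.142 for nuclear-encoded respiratory chain. Low-fat 3 had the highest length slope of the 16 libraries (0.216).

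Over all genes, edgeR called 0 of 17833 between low fat and control, with 1644 at an unadjusted p under 0.05 and a smallest adjusted p of 0.53. The unadjusted count was 2656 without control 1, 3664 without control 3, 1008 without control 4, 996 without low-fat 2, 605 with the library number as a covariate and 609 with the compared groups alone. DESeq2 called 4, which were Slc7a2, a cationic amino acid transporter (476.7 ± 82.7 against 1170 ± 607 CPM), AB124611, Gm14097 and 4930544F09Rik, all chosen after their values were seen, and with no low-count filter DESeq2 called 0. Without control 3, edgeR called 109 genes, 103 higher and 6 lower with low fat. The remaining controls then held 95.5 to 279 CPM of the kidney genes and the low-fat libraries 1090 to 3320 CPM, with no overlap. The libraries separated completely for 2.59% of genes, against 2.86% by chance.

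High protein was compared with low protein, the 2 extremes of protein intake, a contrast that uses no control library as reference. Amino acid catabolism was higher with high protein in 40 of 54 genes (median log2 fold change 0.18), with Oat, ornithine aminotransferase, at 1084 ± 282 against 533.9 ± 96.6 CPM (SD, n = 4) and Ivd, of leucine breakdown, at 297.2 ± 21.2 against 221.9 ± 16.9 CPM. Urea cycle genes were higher in 7 of 8 (median 0.56), with Ass1 at 4395 ± 1050 against 2355 ± 344 and Slc25a13 at 213.1 ± 14.9 against 171.8 ± 6.08 CPM. Of cytosolic ribosomal proteins 77 of 77 were higher (median 0.25), with Rplp2 at 1.35-fold and Rpl27 at 1.27-fold, and of the nuclear-encoded respiratory chain 60 of 60 (median 0.22), with Ndufb10 at 1.25-fold and Uqcrb at 1.26-fold. The library highest for both lists, high-protein 4, had the lowest length slope (-0.113). B cell markers were lower in 9 of 11 (median -0.88), with Ighd, an antibody heavy chain gene, at 0.351 ± 0.21 against 1.104 ± 0.568 CPM.

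Camera called 11 lists, 8 higher and 3 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.392. Amino acid catabolism (camera adjusted p = 4.12e-09, adjusted p = 0.43 with an estimated correlation) kept the call with any 1 library left out. So did urea cycle (in the same order 2.39e-05 and 0.392), cytosolic ribosomal proteins (9.66e-23 and 0.439) and nuclear-encoded respiratory chain (3.54e-16 and 0.439). The same held for periportal hepatocyte (3.18e-05 and 0.392), endothelial cell (0.000145 and 0.682) and B cell (3.18e-05 and 0.392). Periportal hepatocyte genes were higher in 11 of 14, with the glutaminase Gls2 at 587.4 ± 154 against 341.4 ± 17.5 CPM, and endothelial cell markers in 16 of 17, with Bmp2 at 1.59-fold and Dnase1l3 at 1.25-fold. Adjusted over the list alone, 4 members of amino acid catabolism, 3 of urea cycle, 5 of B cell and 1 of periportal hepatocyte passed.

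Gluconeogenesis was higher in 9 of 10 (camera adjusted p = 0.00506, adjusted p = 0.682 with an estimated correlation), with Ppargc1a at 3.31-fold and Pck1 at 2.27-fold. For gluconeogenesis the adjusted p was 0.162 without high-protein 4. Lipogenesis was lower in 18 of 21 (0.00364, with an estimated correlation adjusted p = 0.692), with the elongase Elovl5 at 160.6 ± 17.7 against 360.4 ± 119 CPM and Pgd, of the pentose phosphate pathway, 1.56-fold lower. For lipogenesis the adjusted p was 0.213 without low-protein 4. Glycolysis and ChREBP targets were lower in 10 of 13 (0.0444, with an estimated correlation adjusted p = 0.439), with Mlxipl, which encodes ChREBP, 1.52-fold and the pyruvate kinase Pklr 2.09-fold lower. The call of glycolysis and ChREBP targets was lost without low-protein 4 (adjusted p = 0.398), low-protein 3 (0.0511), high-protein 1 (0.0519) or high-protein 2 (0.121). It was also lost without control 3 (0.0733) or without low-fat 1 (0.0553), 2 (0.0566), 3 (0.0663) or 4 (0.0541), which enter only through the shared fit. Mitochondrially encoded genes were higher in 12 of 13 (0.0444, with an estimated correlation adjusted p = 0.851). For mitochondrially encoded genes the adjusted p was 0.888 without high-protein 3, 0.371 without low-protein 2, 0.0654 without low-protein 1, 0.0697 without control 4 and 0.051 without low-fat 3. Of pericentral hepatocyte markers, not called as a list, 3 passed adjusted over the list alone. Among them Slc1a2, a glutamate transporter, was at 150.6 ± 39.4 against 80.22 ± 8.39 CPM (0.00391 adjusted over the list alone).

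Over all genes, edgeR called 0 of 17833 between high and low protein, with 922 at an unadjusted p under 0.05 and a smallest adjusted p of 0.787, while DESeq2 called 25. At an unadjusted p under 0.05 were 1999 genes without control 4, 610 without low-protein 3, 527 without high-protein 4 and 2034 with the compared groups alone. The smallest p of edgeR belonged to Alas1 (chromosome 9, 106233455 to 106248654), the rate-limiting enzyme of haem synthesis, at 1029 ± 409 against 233.3 ± 112 CPM. Arid5b was at 92.48 ± 30.0 against 33.28 ± 3.24 CPM and Noct, a clock-controlled phosphatase, at 117.4 ± 52.0 against 26.31 ± 23.9 CPM (log2 fold change 2.16, and 2.99 without low-protein 2), and all of these were chosen after their values were seen. Without high-protein 3, edgeR called 2 genes, Btbd19 and Bud13. The libraries separated completely for 6.61% of genes, against 2.86% by chance.

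**Figure D3:**
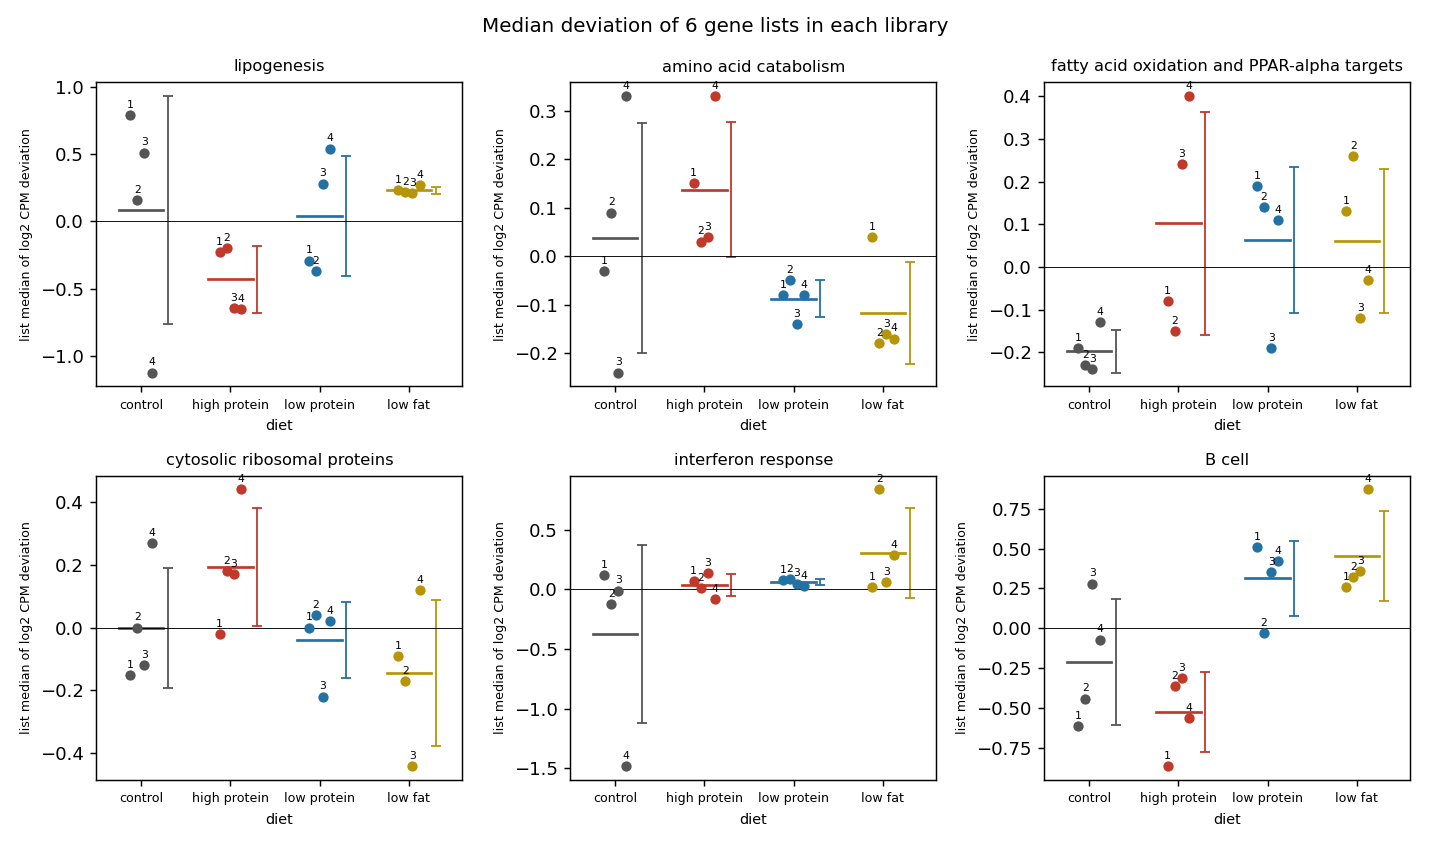
Median deviation of the members of 6 gene lists from their mean over all libraries, in log2 CPM, for each library (numbered points), with the mean and SD of each diet (line and bar). For cytosolic ribosomal proteins high-protein 4 is at 0.44 and low-fat 3 at -0.44, and for interferon response control 4 is at -1.48.

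High protein was compared with low fat, a pair that differs in protein, carbohydrate and fat. Cytosolic ribosomal proteins were higher with high protein in 77 of 77 (median log2 fold change 0.35), with Rplp2 at 80.6 ± 17.2 against 53.65 ± 5.71 CPM (SD, n = 4) and Rps21 at 1.61-fold, and the nuclear-encoded respiratory chain in 60 of 60 (median 0.32), with Cox7a2 at 1.35-fold and Ndufb10 at 1.31-fold. The libraries at the ends of both lists were also at the ends of the length slope, with high-protein 4 the highest for the lists (0.44 and 0.48) and the lowest in slope (-0.113) and low-fat 3 the lowest for the lists (-0.44 and -0.35) and the highest in slope (0.216). Control 4 was at 0.27 for cytosolic ribosomal proteins, with a slope of 0.11. Xenobiotic metabolism was higher in 18 of 21 (median 0.50), with Cyp2a5 at 1968 ± 1280 against 348.9 ± 181 and Cyp2c54 at 395.3 ± 55.6 against 248.8 ± 21.3 CPM. Unfolded protein response genes were lower in 15 of 16 (median -0.53), with the chaperone Hspa5 at 795.2 ± 270 against 1429 ± 559 CPM and Sel1l 1.44-fold lower. Lipogenesis was lower in 16 of 21 (median -0.70), with Elovl5 2.27-fold lower, although Dgat2, of triglyceride synthesis, was 1.61-fold higher. B cell markers were lower in 10 of 11 (median -1.31), with the antibody heavy chain gene Ighm at 2.983 ± 0.579 against 7.38 ± 4.63 CPM.

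Camera called 16 lists, 8 higher and 8 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.411. Kept with any 1 library left out were amino acid catabolism (camera adjusted p = 5.68e-08, adjusted p = 0.411 with an estimated correlation), urea cycle (0.000128), lipogenesis (0.000804, with an estimated correlation adjusted p = 0.43), unfolded protein response (2.45e-05), xenobiotic metabolism (1.43e-05), circadian clock (0.00341), cell cycle (0.000579, with an estimated correlation adjusted p = 0.488), cytosolic ribosomal proteins (9.06e-29), nuclear-encoded respiratory chain (4.67e-19), cholangiocyte (0.000579) and B cell (6.81e-05). Those with no other p given had an adjusted p of 0.411 with an estimated correlation. Amino acid catabolism was higher in 42 of 54, with Gpt, alanine aminotransferase, at 571.7 ± 122 against 356 ± 22.1 and Sardh at 1110 ± 131 against 816 ± 87.4 CPM. Urea cycle genes were higher in 8 of 8, with Slc25a13 at 213.1 ± 14.9 against 160 ± 11.5 CPM and Arg1, arginase 1, at 1.69-fold. Circadian clock genes were higher in 15 of 20, with Ciart at 31.17 ± 11.1 against 3.539 ± 3.74 CPM (log2 fold change 3.15, and 4.2 without low-fat 4), while Npas2, a partner of BMAL1, was 7.16-fold lower. Cell cycle genes were lower in 23 of 26, with Cdk1 1.66-fold and Aurkb 2.33-fold lower. Cholangiocyte markers were lower in 12 of 12, with Cftr 3.4-fold lower, and with the kidney score as a covariate the cholangiocyte difference turned to the other direction (adjusted p = 0.658). Adjusted over the list alone, 9 members of lipogenesis, 8 of circadian clock, 6 of B cell, 5 of amino acid catabolism, 5 of xenobiotic metabolism, 2 of periportal hepatocyte and 1 of urea cycle passed. Of pericentral hepatocyte, which was not called as a list, 4 passed, with Slc1a2, Oat and Cyp2e1 higher and Slc1a4 lower.

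Gluconeogenesis was higher in 9 of 10 (camera adjusted p = 0.0151, adjusted p = 0.494 with an estimated correlation), with Pck1 at 2.08-fold and Got1 at 3.18-fold (log2 fold change 1.67, and 1.05 without high-protein 4). For gluconeogenesis the adjusted p was 0.164 without high-protein 4. Periportal hepatocyte genes were higher in 10 of 14 (0.0122, with an estimated correlation adjusted p = 0.411), with Gls2 at 1.69-fold. For periportal hepatocyte the adjusted p was 0.0751 without high-protein 4 and 0.102 with the kidney score as a covariate. Interferon response was lower in 25 of 30 (0.00626, with an estimated correlation adjusted p = 0.663), with Ifit2 1.64-fold lower. For interferon response the adjusted p was 0.573 without low-fat 2. T and NK cell markers were lower in 13 of 13 (0.0151, with an estimated correlation adjusted p = 0.411). For T and NK cell the adjusted p was 0.383 without low-fat 2, 0.0547 without high-protein 1 and 0.0843 with the kidney score as a covariate. Male-biased liver genes were lower in 17 of 22 (0.0189, with an estimated correlation adjusted p = 0.693). For male-biased liver genes the adjusted p was 0.85 without high-protein 4, 0.129 without high-protein 1, 0.0649 without low-fat 1, 0.0619 without low-fat 3, 0.0509 without low-fat 4 and 0.0655 without control 3.

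Over all genes, edgeR called 0 of 17833 between high protein and low fat, with 1620 at an unadjusted p under 0.05 and a smallest adjusted p of 0.277, while DESeq2 called 81 and limma-voom with quality weights 1. The unadjusted count was 3092 without control 4, 1023 without high-protein 4, 1053 without low-fat 3 and 2836 with the compared groups alone. Small p-values in edgeR belonged to Noct (chromosome 3, 51224447 to 51251644) at 117.4 ± 52.0 against 12.86 ± 3.08 CPM and to Cyp2a5, and Alas1 was at 1029 ± 409 against 260.4 ± 110 CPM. Noct and Alas1 were chosen after their values were seen. Slc1a2 was at 150.6 ± 39.4 against 75.83 ± 13.0 CPM (0.00173 adjusted over the list alone). edgeR called 19 genes without control 4, 16 with the 8 compared libraries alone, 1 (Bud13) without high-protein 3 and 2 (Slc1a2 and Srms) with the library number as a covariate. The libraries separated completely for 8.22% of genes, against 2.86% by chance.

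**Figure D4:**
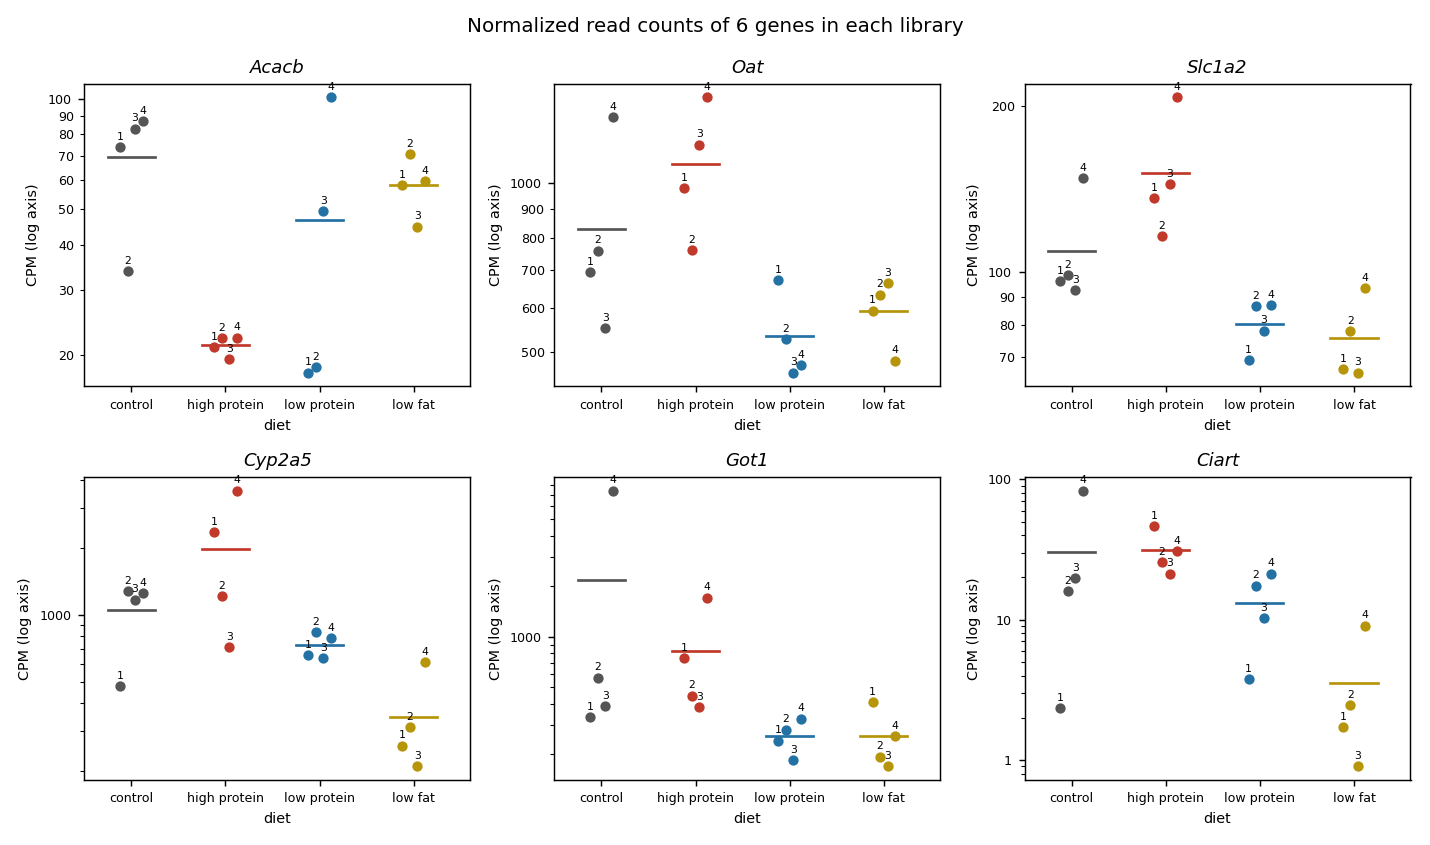
TMM-scaled CPM of Acacb, Oat, Slc1a2, Cyp2a5, Got1 and Ciart in each library (numbered points, log axes) with the mean of each diet (line). Slc1a2 averages 150.6 CPM with high protein and 75.83 CPM with low fat, and control 4 has 7400 CPM of Got1.

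Low fat was compared with low protein, both high in carbohydrate. Unfolded protein response genes were higher with low fat in 16 of 16 (median log2 fold change 0.36), with Hspa5 at 1429 ± 559 against 890 ± 266 CPM (SD, n = 4) and Creld2 at 2.28-fold (log2 fold change 1.19, and 0.59 without low-fat 2). Xenobiotic metabolism was lower in 18 of 21 (median -0.51), with Nr1i3, the nuclear receptor CAR, at 23.71 ± 3.93 against 41.6 ± 6.6 CPM and Cyp2c54 1.48-fold lower. Circadian clock genes were lower in 15 of 20 (median -0.42), with Bhlhe41 4.54-fold lower and Npas2 3.93-fold higher. Cell cycle genes were higher in 23 of 26 (median 0.31), with the proliferation marker Mki67 at 1.71-fold.

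Camera called 12 lists, 7 higher and 5 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.754. Unfolded protein response (camera adjusted p = 1.94e-05), xenobiotic metabolism (2.4e-05), circadian clock (0.00197) and cell cycle (0.000124), each with an adjusted p of 0.754 with an estimated correlation, kept the call with any 1 library left out. In xenobiotic metabolism 1 member, Nr1i3, passed adjusted over the list alone. Without low-fat 2 the adjusted p was 0.497 for interferon response (higher in 29 of 30, 0.000108, with Ifit2 at 1.4-fold), 0.843 for Kupffer cell (higher in 12 of 13, 0.0224, with Csf1r at 1.22-fold), 0.809 for T and NK cell (higher in 9 of 13, 0.0138) and 0.0611 for endothelial cell (higher in 16 of 17, 0.0384). Without low-fat 3 it was 0.85 for cytosolic ribosomal proteins (lower in 70 of 77, 1.94e-05, with Rps29 at 0.663-fold), 0.797 for nuclear-encoded respiratory chain (lower in 49 of 60, 0.00243, with Ndufa6 at 0.838-fold) and 0.0723 for cholangiocyte (higher in 11 of 12, 0.00241, with Prom1 at 2.06-fold and Krt19 at 1.45-fold), and this library had the highest length slope (0.216). Pericentral hepatocyte markers were lower in 11 of 14 (0.0384), with Rnf43 2.24-fold and Cyp2e1 1.29-fold lower. For pericentral hepatocyte the adjusted p was 0.0538, 0.131 and 0.0583 without low-protein 1, 2 and 3. It was 0.13, 0.0627 and 0.0926 without low-fat 1, 2 and 4. The list nuclear-encoded respiratory chain also had 0.0555 without low-protein 2, 0.228 without low-protein 4 and 0.0654 without low-fat 2. The list Kupffer cell also had 0.0518 without low-protein 1, 0.0692 without low-protein 2, 0.247 without low-protein 3 and 0.0569 with the kidney score as a covariate. The list endothelial cell also had 0.0671 without low-protein 1, 0.182 without low-protein 2, 0.151 without low-fat 1, 0.112 without low-fat 4, 0.0542 without control 3 and 0.053 without high-protein 1. The list T and NK cell also had 0.0821 without low-protein 1 and 0.0679 without low-protein 3, and cholangiocyte had 0.0569 with the kidney score as a covariate. With an estimated correlation the adjusted p of these lists was 0.754 for interferon response, Kupffer cell, T and NK cell, cholangiocyte and pericentral hepatocyte, 0.907 for cytosolic ribosomal proteins, 0.91 for endothelial cell and 0.923 for nuclear-encoded respiratory chain. edgeR called 0 of 17833 genes, with 425 at an unadjusted p under 0.05 (2.4%, below that level) and a smallest adjusted p of 1, and DESeq2 called 0. Without control 3 or 4 the unadjusted count was 755 and 916. With the compared groups alone it was 1681, and each count between diets rose while each against control fell. The shared fit pools wide controls with tighter diets, so its unadjusted counts cannot be set against chance. The smallest p belonged to Eva1a, a regulator of autophagy chosen after its values were seen, at 51.89 ± 8.13 against 81.07 ± 6.48 CPM. The libraries separated completely for 4.49% of genes, against 2.86% by chance.

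The 3 diets were also set beside each other through the shared control. Across 17833 genes, the fold changes of high and low protein correlated at 0.61, those of high protein and low fat at 0.44 and those of low protein and low fat at 0.72, where genes are not independent replicates. Simulated counts with 1 mean per gene in all libraries gave a correlation of 0.76 in each case. The controls were simulated too, with only their spread taken from the real ones and each gene drawn independently. Profiles that many genes share in a real control are therefore missing from this reference. Leaving out 1 control moved the observed correlations, to 0.5 without control 4 and 0.77 without control 3 for high and low protein, 0.25 and 0.74 for high protein and low fat, and 0.5 and 0.87 for low protein and low fat. The covariances were 0.159, 0.118 and 0.212, against 0.198 in the simulation. With the controls divided 2 and 2 between the diets, the mean correlations were -0.31, -0.30 and -0.12. The test of the 3 diets against control together called 0 of 17833 genes in edgeR, with 1175 at an unadjusted p under 0.05 and a smallest adjusted p of 0.63, while DESeq2 called 79. Without control 1, 3 or 4 the unadjusted count was 1849, 2749 and 1965.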

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

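The splits of the libraries and the tests of GC content, RNA degradation, cell composition and library order were fixed before their results were seen, and the tests on kidney transcripts and on control 4 were chosen only after the result was seen, as were the correlation limit in the test of cell composition and the use of the SE in the test of library order.

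Values were looked at again where 1 of the 4 libraries of a diet lay far from the other 3, by Dixon's ratio at the 0.05 level. This held for 57 of 644 groups of 4 values (nominally 32), but 40 were CPM of genes named here, so chance cannot be judged. In control 4, 18 values stood apart. These were the list medians of gluconeogenesis (1.07) and interferon response (-1.48) and the CPM of Sdsl (116), Ass1 (9960), Got1 (7400), Ppargc1a (148), Sds (2140), Cdkn1a (554), Socs2 (361), Tat (21300), Pck1 (16300), Cyp2b10 (32.9), Per1 (340), Slc1a2 (148), Arg1 (3350), Sesn1 (382), Atf3 (162) and Amy2a5 (7.61).

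In the other controls, control 1 stood apart for Cyp2a5 (478 CPM) and Elovl3 (153 CPM), control 2 for mitochondrially encoded genes (-0.31), and control 3 for Kupffer cell (-0.06) and Prom1 (9.49 CPM). With high protein, replicate 1 stood apart for Ifit2 (2.76 CPM), replicate 2 for the growth hormone and IGF axis (0.16), replicate 3 for Aurkb (0.622 CPM) and replicate 4 for gluconeogenesis (0.47), Cox5a (86.8 CPM) and Sdhb (246 CPM). With low protein, replicate 1 stood apart for Gpt (360 CPM), Atf3 (4.55 CPM) and Fosb (4.45 CPM), replicate 2 for acute phase (0.09), replicate 3 for female-biased liver genes (-1.5), cytosolic ribosomal proteins (-0.22), Rplp1 (155 CPM), Rps6 (260 CPM) and Cela2a (2.1 CPM), and replicate 4 for periportal hepatocyte (-0.15), Creld2 (62.5 CPM) and Mki67 (6.36 CPM).

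With low fat, replicate 1 stood apart for amino acid catabolism (0.04), replicate 2 for its total of 112.8 M counts (112789127), cholesterol synthesis (-0.24) and Gbp2 (16.2 CPM), and replicate 3 for the difference of long from short genes (0.349), glycolysis and ChREBP targets (-0.1), Cftr (1.72 CPM) and Myc (58.1 CPM). Replicate 4 stood apart for NRF2 targets (-0.31), B cell (0.87), Arid5b (126 CPM), Cyp4a12a (188 CPM), Igkc (11 CPM), Pgd (51.4 CPM), Mki67 (2.41 CPM) and Btbd19 (6.77 CPM).

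Control 4 differed from the other controls in genes of glucocorticoid and fasting responses. Its median deviation over 22 such genes was 3.53 log2 units, against at most 1.36 in any other library, with Igfbp1 at 9720 CPM, but the list was written after this profile was seen and 10 of its genes are in the fixed lists. A female animal under a male label was argued against by Xist at 0.37 CPM and Y-linked genes at 245 CPM, against a median of 166 in the other 15 libraries. Kidney RNA was argued against by a summed kidney level of 8.13 log2 CPM, below the median of the other libraries. A stress or fasting state at collection may lie behind the profile, as a hypothesis that these data cannot test.

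Kidney transcripts made up 0.000273% of counts in high-protein 1 and 0.563% in control 3. Reads of 1 kidney library assigned to the others would keep the same proportions among the kidney genes, whereas over 105 pairs of 15 libraries the median chi-square per degree of freedom was 45.7 (3.6 to 417). Diet stays open, since the smallest exact permutation p of the 3 diets against control was 0.143, and 0.029 for the kidney level with low protein and with low fat without control 3. Kidney tissue or RNA carried over at dissection may be a source, as a hypothesis with no test of its own here.

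The length slope between high protein and control was -0.115. Library order cannot be told apart from diet here, since the numbers of the high-protein libraries (1, 2, 6 and 13) all lie below those of the controls (15, 16, 18 and 24). With the number as a covariate the difference was -0.079 with an SE of 0.097, and the correlation within groups was 0.15 (permutation p = 0.632). With exonic length, GC content and mean expression as further predictors it was -0.043 (exact permutation p = 0.629), 38% of its size, and without 5256 genes that follow a marker list it was -0.104 (-0.092 and -0.113 at correlation limits of 0.5 and 0.7), so neither is decided. RNA degradation met its written criterion, with -0.165 on exonic against -0.055 on genomic length in 1 model, but both lie inside the spread (exact permutation p = 0.429 and p = 0.514) and the lengths have different scales. An effect of diet could stay among the open explanations; the test without called genes was void, as 0 genes were called by edgeR (1109 at an unadjusted p under 0.05, 1 by DESeq2).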

How the results depend on the processing

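Leaving out control 3 and 4 or control 4 and high-protein 4, single libraries for the kidney level, the kidney score, leaving out kidney-associated genes or libraries outside a comparison, and DESeq2 with no low-count filter were tests chosen only after the result was seen; the cause of each change below was not tested. The genes changed by edgeR stayed at 0 with other factors, filters and the kidney score. DESeq2 gave 1 for high protein, 10 for low protein and 4 for low fat against control. It gave 25 for high against low protein, 81 for high protein against low fat and 79 for any diet. With no low-count filter the counts for these pairs were 1, 11, 0, 25 and 78, and 0 for low fat against low protein. For high protein against low fat the genes changed were 2 with the library number, 16 in the compared groups alone, 19 without control 3 and 4 and 1 with limma-voom quality weights. Without single libraries the ranges were 0 to 109 (low fat against control, highest without control 3), 0 to 2 (high against low protein, without high-protein 3), 0 to 19 (high protein against low fat, without control 4) and 0 to 1 (any diet, Bud13 without high-protein 3).

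The gene lists called fell to 0 in each comparison with an estimated correlation and to 0 with fry, except 2 for low fat against control. Gene lists for high protein against control ran from 8 to 18 without single libraries, the highest without control 4, and were 18 without control 3 and 4; for low fat against low protein they ran from 6 (without low-fat 2) to 13 (without low-protein 3 or 4). The direction of male-biased liver genes against control turned without control 3 and 4, with an adjusted p from camera of limma of 0.0903 for low protein and 0.396 for low fat. For low protein it also turned without control 4 and high-protein 4 (0.986). With the kidney score, cholangiocyte turned for low fat against control (0.432) and for high protein against low fat (0.658). Over the single lists, 4269 results kept direction and side of the threshold, 221 lost and 167 gained a call and 5 turned.

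The length slope of low fat against control was -0.101 on exonic length, -0.013 at 5 CPM or more, 0 at a prior count of 0.5 and -0.04 without kidney-associated genes (length bins -0.023), and ran from -0.053 to 0.032 (length bins -0.062 to 0.066) without single libraries. The length slope of low protein against control was 0.006 without control 3 and 4 (length bins 0.011). The kidney level of high protein against control ran from -1.83 to 1.1 without single libraries, and turned without high-protein 1 (1.1) and without control 3 (0.39). The overlap between comparisons was -0.31, -0.3 and -0.12 with the controls split. The length slope without called genes could not be computed, as 0 genes were called.

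In high protein against control, Lyz2 was at -0.04 and Cd9 at 0.04 with the library number, Cd9 at 0.12 without control 3 and 4, and Sdsl at 0.4 with the library number, 0.46 without control 3 and 4, 0.28 without control 4 and high-protein 4 and 0.29 with quality weights (-1.82 to 0.51 without single libraries). In low protein against control, Mup3 was at -0.08 with the library number and -0.06 without control 3 and 4, and Cdkn1a at 0.02 without control 3 and 4, 0.25 without control 4 and high-protein 4 and 0.06 with quality weights (-3.55 to 0.25). Atf3 in the same comparison was at 0.73 without control 3 and 4, 0.72 without control 4 and high-protein 4 and 0.45 with quality weights (-4.26 to 0.72). The log2 fold change of Ercc1, at 46 to 175 counts per library, kept its sign in 139 results and turned in 35. For high protein against control Ercc1 was at 0 with upper-quartile factors, 0.02 without control 3 and 4, 0.01 with quality weights (-0.13 to 0.09), and for low protein against control -0.17 to 0.04 without single libraries. For low fat against control it was -0.01 with RLE factors, 0 with no filter, -0.09 with the library number, -0.03 with the kidney score, -0.08 without control 4 and high-protein 4, -0.02 with quality weights and -0.03 with DESeq2 (-0.11 to 0.13). For high against low protein it was -0.01 with the library number (-0.03 to 0.15), and for high protein against low fat 0.02 with the kidney score, 0.08 without control 4 and high-protein 4 and 0.03 with quality weights (-0.11 to 0.09). For low fat against low protein it was -0.03 to 0.18.

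The replicate numbers do not pair the libraries: 8 of 24 same-number pairs had a correlation over 0.1 (-0.329 to 0.411) and 5 of 16 libraries correlated best with their own number. With the replicate number as a block the genes changed stayed at 0 in each comparison, and recruited macrophage and neutrophil between high protein and control had an adjusted p of 0.0582.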

Other observations

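The splits of the libraries were fixed before their results were seen; the reading of the controls' correlations, of the kidney levels of single splits and of the unadjusted counts over the splits were tests chosen only after the result was seen. Several fixed lists were called in none of the comparisons by camera. For high protein against low fat the adjusted p was 0.124 for ATF4 targets, 0.564 for NRF2 targets, 0.585 for bile acid synthesis and transport, 0.6 for female-biased liver genes, 0.143 for acute phase, 0.512 for immediate early genes, 0.6 for stellate cell and fibroblast, 0.199 for exocrine pancreas, 0.6 for cholesterol synthesis, 0.6 for growth hormone and IGF axis and 0.707 for p53 targets. Signs differed for p53 targets (camera higher, median 0.05, mean -0.02) and for stellate cell and fibroblast (camera lower, median 0.03, mean -0.13). In the p53 targets, 2 members passed adjusted over the list alone, Dcxr at 96.75 ± 19 against 66.32 ± 7.8 CPM (SD, n = 4; edgeR) and the death receptor Fas at 11.56 ± 1.6 against 17.16 ± 2.65 CPM. In the growth hormone and IGF axis, 2 passed, Igfbp4 at 2175 ± 288 against 1411 ± 241 CPM and the transcription factor Stat5a at 8.491 ± 0.561 against 15.15 ± 4.25 CPM. For low protein against control, 3 immediate early genes passed adjusted over the list alone, Atf3, Fosb and Myc, with Myc at 10.36 ± 7.25 against 116.9 ± 134 CPM. Without control 4 the log2 fold change of Myc went from -3.49 to -2.32, that of Fosb from 2.41 to 3.16 (0.83 without low-protein 1), and that of Atf3 turned from -3.86 to 0.72. For low fat against control, 2 genes of exocrine pancreas passed adjusted over the list alone, the amylase Amy2a5 at 0.9496 ± 0.489 against 2.882 ± 3.16 CPM and the elastase Cela2a at 0.907 ± 0.166 against 1.653 ± 0.666 CPM. The log2 fold change of Amy2a5 went from -1.6 to -0.49 without control 4.

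Of the tissue lists added after seeing the data, kidney had the widest range of medians per library, from -6.97 in high-protein 1 to 2.94 in control 3 (log2 units). Adrenal gland (2 genes) ran from -1.47 in control 4 to 1.9 in high-protein 2, and gut epithelium (3 genes) from -1.38 in control 4 to 0.56 in low-fat 1. Adipose tissue (5 genes) ran from -0.19 in high-protein 2 to 0.35 in low-protein 3, and lung (5 genes) from -0.61 in low-fat 3 to 0.68 in high-protein 4. Of skeletal muscle, 0 genes passed the low-count filter.

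Other divisions of the same libraries were tested for the count of genes past the threshold. As the real count was 0, each of the 35 splits of each comparison and each of the 100 drawn splits of the 4 diets gave as many whatever the data, so this count is void as a test and says nothing about chance. The highest other counts were 255 for high protein against control, 0 for low protein against control, 253 for low fat against control, 0 for high against low protein, 9 for high protein against low fat, 0 for low fat against low protein and 8 for any diet, where edgeR gave 1109, 1262, 1644, 922, 1620, 425 and 1175 genes at an unadjusted p under 0.05 and DESeq2 called 1, 10, 4, 25, 81, 0 and 79. The split with 255 genes set high-protein 1 and control 1, 2 and 4 against the rest, and that with 253 set low-fat 1 and the same controls against the rest, which points to a structure of these libraries. Of the other splits that put control 3 apart from the other 3 controls, in each comparison with control, 0 genes were called. Both groupings hold the 4 libraries with the least kidney transcripts of their comparison, with 2.73 CPM in high-protein 1, 1090 CPM in low-fat 1 and 95.5 to 279 CPM in these controls. A further split, of high-protein 1 and 3 with control 1 and 2, called 146 genes and does not follow the kidney level, since control 4 (279 CPM) was below high-protein 3 (450 CPM). The real count of genes at an unadjusted p under 0.05 was reached, the real split included, by 32 of 35 splits for high protein, 28 for low protein and 20 for low fat against control, 2 for high against low protein, 1 for high protein against low fat, which is the real split itself (1620, next 1558), 3 for low fat against low protein and 25 of 100 for any diet. The deviations of controls from the mean of the libraries of the other diets correlated at 0.44 between control 1 and 2. They correlated at -0.36 and -0.39 between control 3 and these. Their variances were 0.32, 0.4, 0.46 and 1.53 for control 1 to 4.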
